A study of Homo sapiens with 4 samples.

How the data were processed

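H3K27me3 chromatin immunoprecipitation and sequencing was done in HaCaT keratinocytes cultured for 12 hours with AKBA or with DMSO, per the labels. The 4 samples are 1 H3K27me3 library and 1 input DNA library for each condition, and each H3K27me3 library has 1 peak list, so peaks were called per library. Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was sonicated, and libraries were amplified and size-selected on a gel before sequencing. Per the submitters' processing notes the genome build was hg19 and the tools named were BWA, STAR and MACS2, with no version. How the input DNA entered the calling, the peak threshold, the treatment of duplicate reads and any filter are not given in the sources used here. The deposited peak lists give a chromosome, start, end, peak name and 1 score per peak, without a header. The score that the authors deposited runs from 2.00 to 18.7 in the DMSO list and from 2.03 to 14.3 in the AKBA list, and whether it is a fold enrichment or a −log10 p-value or q-value is not given. It was therefore used to rank and filter peaks, and scores of different lists were not subtracted or divided. The one setting that applied a common score minimum to both lists assumes the same scale in both.

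The narrowest peak was 160 bp and the smallest gap between neighbouring peaks 641 bp in the DMSO list, against 214 and 857 bp in the AKBA list. A minimum width and a joining distance that differ between the libraries can change numbers and widths of peaks before any comparison. The gene table at hand was that of assembly GRCh38.p14. In the 2 lists together, 229 peaks on 12 chromosomes ended past the last gene of that table, by up to 2.68 Mb on chromosome 9. By general knowledge of the assembly, and not from the files, GRCh38 chromosome 9 ends before the DMSO peak that starts at 139083801, so the coordinates are not those of GRCh38. Because the table's build differs from that of the peaks, no peak was assigned to a gene, and the gene counts, the promoter, exon and intron positions and the gene lists fixed before the data were examined were not analysed here. The lists concerned HOX genes, other developmental transcription factors, keratinocyte differentiation and basal genes, skin inflammation, lipoxygenases, H3K27 methylation machinery, cell cycle inhibitors, housekeeping genes and markers of 4 other cell types.

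Peak numbers, widths and covered bases were computed from the lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp, counted from each side. The counts were checked against bedtools 2.31.1. On simulated data, 3000 copies of DMSO peaks were moved by up to 2 times their width and 2000 peaks were placed clear of all DMSO peaks. The 1617 copies that still overlapped a DMSO peak by direct comparison were found, and none of the 1383 other copies or the 2000 placed peaks was called an overlap. Overlap was set beside 1000 placements of a list at random positions of the same chromosomes, between the first and last peak of both lists, and beside 1000 circular shifts. These describe the 2 lists and do not test the treatment. Covered bases were summed in windows of 1 Mb. Peaks of both lists within 5 kb of each other were joined into domains. Coordinates are 1-based hg19 positions.

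The regions named were fixed by rule before the data were examined: the 3 widest and the 3 highest-scoring peaks of each list, and the 3 windows of 1 Mb with the greatest difference of covered bases in each direction. Domains named in addition, and a peak on chromosome 10 named as the third highest-scoring DMSO peak without an AKBA overlap, were chosen after their values were seen. With 1 library per condition no test across libraries was possible. Exact 95% Clopper-Pearson binomial intervals of shares, and the interval of the ratio of peak numbers derived from them, cover counting error only, treat peaks as independent, and leave out the variation between cultures. Bootstrap intervals of width differences resample peak pairs within the lists, and they too treat peaks as independent and leave out that variation. Depth is unknown, so no detection limit is given. The alternatives were a stricter score, the same number of peaks from each list, merging of peaks within 5 kb, a minimum width of 1 kb, other definitions of overlap, and, chosen after seeing the data, removal of the peaks at the narrowest width of their list.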

Results

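The trimethyl mark on lysine 27 of histone H3 (H3K27me3) was mapped by chromatin immunoprecipitation and sequencing in HaCaT cells. The mark is laid down by a Polycomb repressive complex and is associated with silenced genes. HaCaT is an immortalised line of human keratinocytes, the main cell type of the epidermis. One culture condition contained AKBA and the other the solvent DMSO, and both lasted 12 hours. The abbreviation AKBA is commonly used for an acetylated boswellic acid from frankincense resin, although the labels do not spell it out and the dose is not given in the sources used here. The series holds 4 samples, of which 2 are H3K27me3 libraries with a peak list each and 2 are input DNA with no values used here. Each condition therefore had 1 H3K27me3 library, no difference has a replicate check, and no p-value is given for the treatment. Read numbers are not part of a peak list, so the sequencing depth of both libraries is unknown. A region outside a list was not called by the authors' peak caller and may still carry the mark below the threshold. Regions are named by position in the human genome build hg19, because an hg19 gene annotation was not used here.

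The first comparison asked how much of the genome carried called H3K27me3 after 12 hours with and without AKBA. The AKBA list held more peaks, wider peaks and nearly double the marked sequence of the DMSO list. It held 13155 peaks against 8890, a ratio of 1.48 with a 95% interval of 1.44 to 1.52 that covers counting error only. AKBA peaks covered 14.7 Mb and DMSO peaks 7.57 Mb, a ratio of 1.94. The mean width was 1114 bp in the AKBA list and 851 bp in the DMSO list, and the median widths were 742 and 552.5 bp. The ratio of peak numbers was greater above fixed cut-offs of width. Peaks of at least 2 kb numbered 1847 in the AKBA list and 838 in the DMSO list, a ratio of 2.20. Peaks of at least 5 kb numbered 242 and 70, a ratio of 3.46. These cut-offs are the same in bp for both lists, whereas each width decile began higher in the AKBA list. The widest decile began at 2499 bp in the AKBA list and at 1932 bp in the DMSO list. The counts alone therefore do not show a difference particular to broad peaks. The median peak score, the authors' own value per peak on a scale that the file does not state, was 2.99 in the AKBA list and 3.02 in the DMSO list. Both lists had a fixed narrowest width, 160 bp for 763 DMSO peaks and 214 bp for 1012 AKBA peaks, a ratio of 1.34 that equals the ratio of the median widths to 2 decimals. When the 8890 highest-scoring peaks were taken from each list, AKBA peaks covered 1.55 times the DMSO length. That setting keeps the whole DMSO list and drops the lowest-scoring AKBA peaks, which raised the AKBA median width to 862.5 bp.

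The 3 widest peaks of each list overlapped peaks of the other list, and 2 of the 3 widest AKBA peaks overlapped several DMSO peaks. The widest DMSO peak, on chromosome 12 from 113903489 to 113918076, spanned 14588 bp, and 93.3% of it was covered by 2 AKBA peaks. A peak on chromosome 7 was second widest in both lists, from 1276999 to 1289570 in the DMSO list and from 1276783 to 1291784 in the AKBA list, with widths of 12572 and 15002 bp. The third widest DMSO peak, on chromosome 9 from 139083801 to 139095982, measured 12182 bp and overlapped an AKBA peak of 11812 bp. The widest AKBA peak lay on chromosome 16 from 86525671 to 86545314. It spanned 19644 bp without a break and overlapped 5 separate DMSO peaks, of which the widest measured 5415 bp. Some of the breaks between these DMSO peaks were narrower than 857 bp, the smallest gap anywhere in the AKBA list, whereas DMSO gaps went down to 641 bp. Part of the contrast between 1 peak and several may therefore come from the joining distance. The third widest AKBA peak, on chromosome 1 from 221055612 to 221070509, spanned 14898 bp and overlapped 4 DMSO peaks that covered 59.8% of it.

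**Figure D1:**
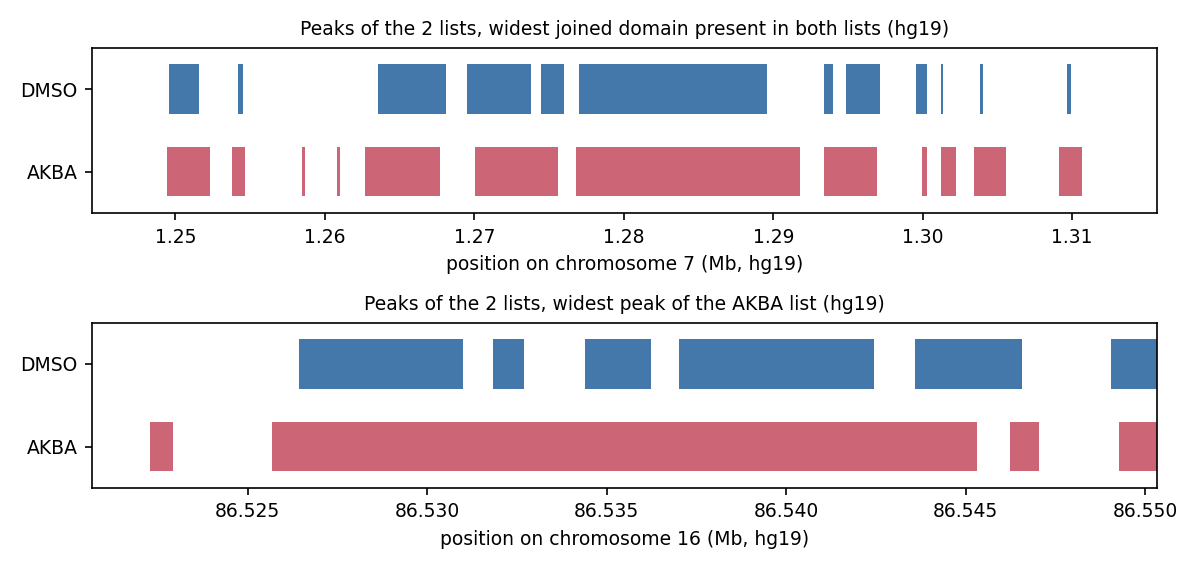
Positions of called H3K27me3 peaks in the DMSO list (blue) and the AKBA list (red), with position in Mb of hg19 on the horizontal axis; each box is 1 peak drawn to scale, and box height carries no value. On chromosome 7 both lists mark a 61.2 kb domain with 12 peaks each, and on chromosome 16 a single AKBA peak of 19644 bp overlaps 5 DMSO peaks, the last of which runs past its end, while boxes at the panel edges continue outside the window. Gaps narrower than 857 bp occur in the DMSO list only.

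The second comparison asked whether the same places were marked. Of the DMSO peaks, 4849 (54.5%, exact 95% binomial interval 53.5 to 55.6%) overlapped an AKBA peak by at least 1 bp, and 4041 did not. Of the AKBA peaks, 4230 (32.2%, interval 31.4 to 33.0%) overlapped a DMSO peak, and 8925 did not. Random placement of the DMSO peaks within their chromosomes gave a mean overlap of 1.06% and at most 1.44% in 1000 draws. Random placement of the AKBA peaks gave 0.701% on average and at most 0.988%. Bases called in both lists came to 4.86 Mb, which was 64.2% of the DMSO bases and 33.2% of the AKBA bases. A single AKBA peak overlapped more than 1 DMSO peak in 583 cases, and a DMSO peak overlapped more than 1 AKBA peak in 84. Wider AKBA peaks and the smallest gaps, 857 bp in the AKBA list and 641 bp in the DMSO list, favour that direction. Joining DMSO peaks across gaps of up to 856 bp left 8307 of the 8890. The 2 counts therefore do not show a fusion of marked regions. The shares depended on the definition of overlap. With a reciprocal overlap of at least 50%, 20.8% of DMSO peaks and 14.0% of AKBA peaks were shared.

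Wide and high-scoring peaks were found in both lists more often than narrow and low-scoring ones. Shared DMSO peaks had a median width of 847 bp and a median score of 3.35, against 352 bp and 2.72 for DMSO peaks without an AKBA counterpart. Shared AKBA peaks had a median width of 1566 bp and a median score of 3.96, against 558 bp and 2.74 for AKBA peaks without a DMSO counterpart. In the widest decile of the DMSO list 99.2% of peaks (interval 98.4 to 99.7%) overlapped an AKBA peak, against 21.6% in the narrowest decile. In the AKBA list the corresponding shares were 93.3% and 6.08%. Of the 838 DMSO peaks of at least 2 kb, 6 had no AKBA overlap, whereas 203 of the 1847 AKBA peaks of that width had no DMSO overlap. Peaks at the narrowest width of their list were shared in 21.1% of DMSO cases and 5.34% of AKBA cases, against 57.7% and 34.4% of the wider peaks.

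**Figure D2:**
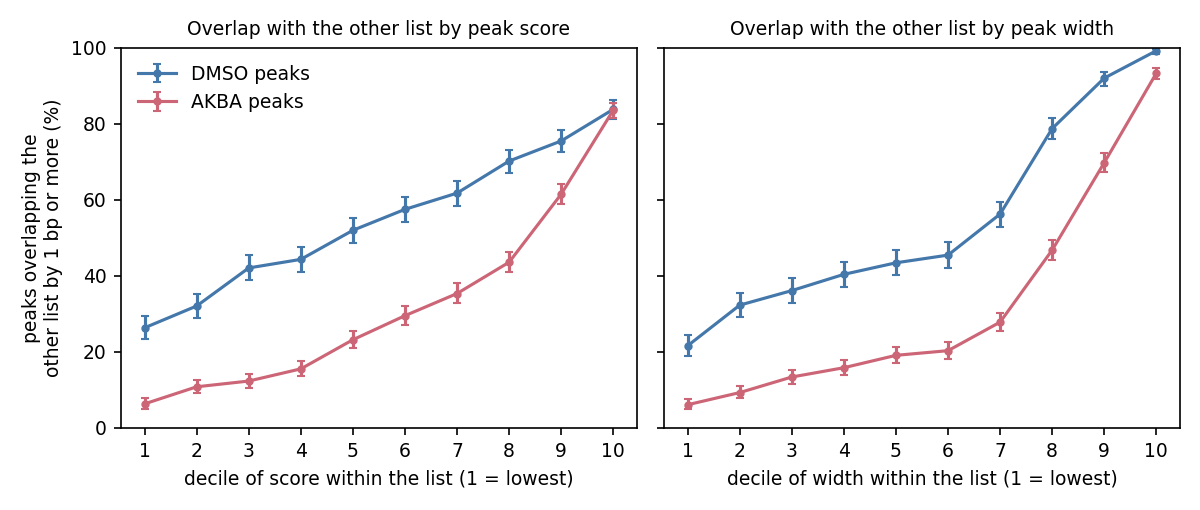
Percentage of peaks that overlap the other list by at least 1 bp, by decile of score (left) and of width (right) within each list; points are DMSO peaks (blue) and AKBA peaks (red) with exact 95% binomial intervals for counting error. Sharing runs from 26.3% to 83.8% of DMSO peaks and from 6.31% to 83.6% of AKBA peaks between the lowest and the highest score decile.

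The 3 highest-scoring AKBA peaks were all at places marked in the DMSO list, whereas 2 of the 3 highest-scoring DMSO peaks had no AKBA counterpart. The top AKBA peak, on chromosome 2 from 105472754 to 105473875, had a score of 14.3 and lay inside a DMSO peak of 4938 bp. The next, on chromosome 7 from 28994197 to 28998753, had a score of 12.9 and shared 84.8% of its width with a DMSO peak of 4129 bp. The third, on chromosome 1 from 218337576 to 218338239, had a score of 12.8 and shared 62.2% of its width with a DMSO peak. In the DMSO list the top peak was on chromosome 1 from 121484395 to 121485467 with a score of 18.7, and the nearest AKBA peak was 346 kb away. The second, on chromosome 15 from 68132341 to 68132713, had a score of 17.1 and lay inside an AKBA peak of 410 bp. The third, on chromosome 7 from 61968844 to 61969608, had a score of 13.6 and lay 2374 kb from the nearest AKBA peak. Of these 3 DMSO peaks, both without an AKBA counterpart lay within 1 Mb of a peak-free stretch of at least 3 Mb, as peaks beside a centromere do.

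The third comparison asked whether the difference was spread over the genome. All 23 chromosomes with peaks, the autosomes and X, held more AKBA than DMSO peaks and more AKBA than DMSO bases. The peak ratio ran from 1.26 on chromosome 4 to 1.63 on chromosome 16, and the ratio of bases from 1.82 on chromosome 17 to 2.82 on chromosome 21. AKBA peaks made up 59.7% of both lists together, and the exact 95% interval of every chromosome's own share included that value. With the same number of peaks from each list, which fixes the overall ratio at 1, 10 of the 23 chromosomes held more AKBA peaks. Both lists had the same dense and sparse chromosomes at the extremes. Chromosome 20 was the densest, with 7.69 DMSO and 11.7 AKBA peaks per Mb of the span between its first and last peak, followed by chromosome 17 with 6.11 and 8.63. Chromosome X was the sparsest, with 0.825 and 1.07 peaks per Mb. Chromosome X also had the highest share of DMSO peaks with an AKBA overlap, 76.2%, against 47.2% on chromosome 10, the lowest.

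**Figure D3:**
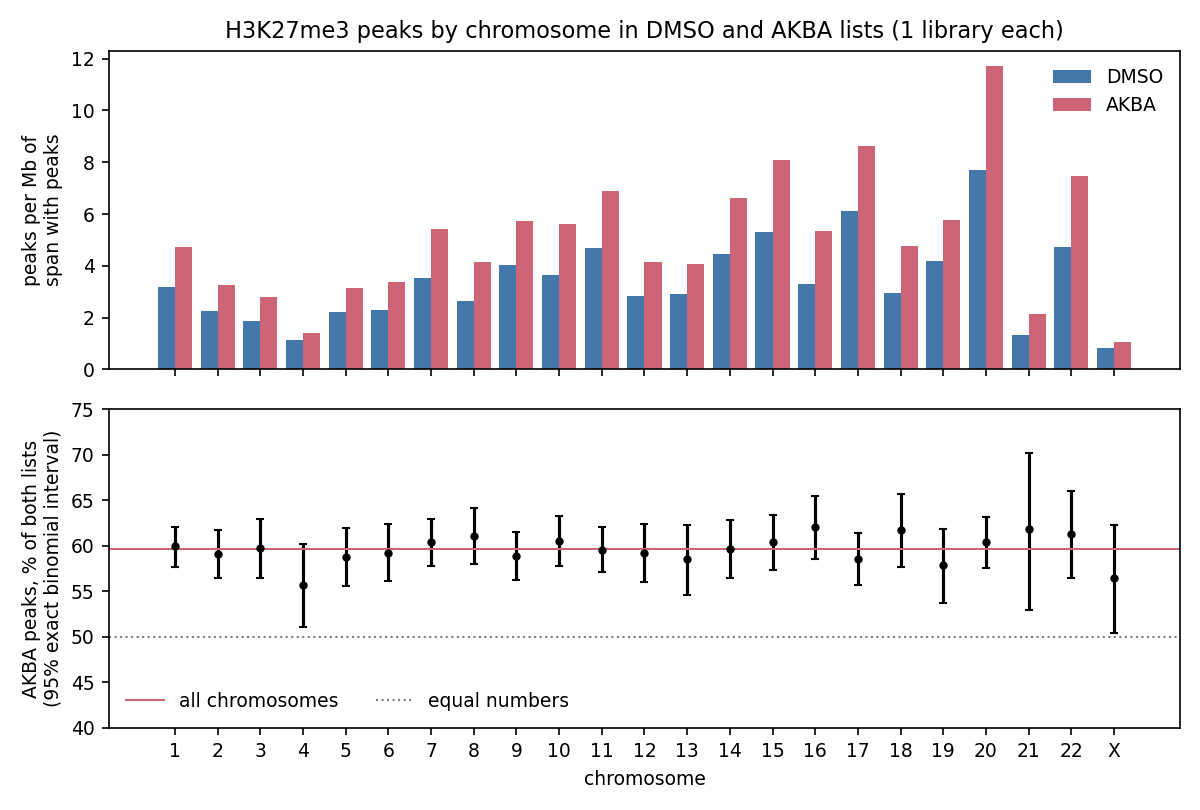
H3K27me3 peaks by chromosome; the upper bars give peaks per Mb of the span between the first and last peak for the DMSO list (blue) and the AKBA list (red), and the lower points give AKBA peaks as a percentage of both lists with exact 95% binomial intervals for counting error on an axis that starts at 40%. Every point lies above 50%, and the interval of every chromosome includes the 59.7% of all chromosomes together (red line).

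In windows of 1 Mb the AKBA list covered more bases in 1826 of the 2122 windows with a peak in either list (86.1%, exact 95% interval 84.5 to 87.5%), and the DMSO list in 296. The share was 75.2% with the same number of peaks from each list. A peak of each list was present in 1766 windows, 260 had AKBA peaks alone and 96 had DMSO peaks alone. The greatest excess in the AKBA list was on chromosome 17 between 77 and 78 Mb, where AKBA peaks covered 99.98 kb and DMSO peaks 42.6 kb. It was followed by 2 windows near the end of the long arm of chromosome 9. Between 138 and 139 Mb AKBA peaks covered 85.9 kb and DMSO peaks 36.5 kb, and between 135 and 136 Mb they covered 88.5 and 40.1 kb. Ranking by the difference in bases favours windows densely marked in both lists. These windows on chromosomes 17 and 9 had 43 to 55 DMSO peaks centred in each. In the other direction, DMSO peaks covered 6.19 kb and AKBA peaks 1.31 kb on chromosome 10 between 42 and 43 Mb. That window holds 10 DMSO peaks. The peak from 42384628 to 42385681, of 1054 bp, lies within 1 Mb of a peak-free stretch of at least 3 Mb, as peaks beside a centromere do. Other peaks can meet that condition too, and the source of the difference in the window was not tested. On chromosome 18 between 18 and 19 Mb the values were 2.63 kb and 0 kb. Between 47 and 48 Mb on chromosome 15 they were 4.13 and 1.64 kb. Whether the windows on chromosomes 18 and 15 lie beside a centromere was not examined. The difference on chromosome 15 was -2.49 kb (AKBA minus DMSO) and -1.21 kb with the stricter score.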

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

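More peaks and more bases with AKBA, the direction of the difference between the lists, held under the alternatives it was computed for, with 1 exception. The other definitions of overlap leave these numbers as they are. The exception is the same number of peaks from each list (the 8890 highest-scoring), which sets the peak ratio to 1 by construction. At that number the ratio of covered bases was 1.55, 10 of 23 chromosomes held more AKBA peaks, 75.2% of windows held more AKBA bases, and 49.8% of DMSO and 42.8% of AKBA peaks were shared. Keeping peaks with a score of at least 3.00 gave 83.0% of windows with more AKBA bases and shares of 60.6% and 37.4%, with 4510 DMSO and 6513 AKBA peaks. Merging peaks within 5 kb gave a base ratio of 1.85 and a share of 35.8% of AKBA peaks. Peaks of at least 1 kb gave ratios of 2.01 for numbers and 2.20 for bases. Shared peaks were 20.8% of DMSO and 14.0% of AKBA peaks at 50% reciprocal overlap, and 63.3% and 37.7% when peaks within 1 kb counted as shared. Without the peaks at the narrowest width, a choice made after seeing the data, they were 57.1% and 33.4%. Restricting to the autosomes and X removed no peak and so tests nothing. The 6 named windows kept their direction, although the difference on chromosome 15 between 47 and 48 Mb went from -2.49 to -1.21 kb with the stricter score. Taking the same number of peaks removes AKBA peaks only, so windows with more DMSO bases could not change direction there. The 12 named peaks remained in the lists under the settings that were run on them. This tests nothing, because their scores of 3.78 or more and widths of 373 bp or more were beyond the reach of those settings. The alternatives planned for promoters and gene lists were not run, because no hg19 annotation was used here. Unknown depth and 1 library per condition limit every comparison.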

Other observations

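The tests of score and of chromosomes for the greater number of AKBA peaks, and of long peak-free stretches for the highest-scoring DMSO peaks, were chosen after the result was seen. Joined across gaps of up to 5 kb, the peaks of both lists formed 4262 domains with peaks of both conditions, 5568 with AKBA peaks alone and 2117 with DMSO peaks alone. Of the 458 domains of at least 10 kb, 441 held peaks of both lists, which the joining of pooled peaks favours for long spans. In 414 of these 441 (93.9%, exact 95% interval 91.2 to 95.9%) AKBA peaks covered more bases, and the median coverage of a domain was 47.3% in the AKBA list and 25.1% in the DMSO list. The widest common domain lay on chromosome 7 from 1249430 to 1310651, with 38.3 kb of AKBA and 29.5 kb of DMSO peaks. The next were on chromosome 8 from 11528699 to 11578930, with 22.2 and 17.9 kb, and on chromosome 3 from 147072306 to 147115989, with 28.2 and 18.2 kb. The widest AKBA domain without a DMSO peak held 4 peaks on chromosome 2 from 127417542 to 127432730, and the widest DMSO domain without an AKBA peak held 3 peaks on chromosome 9 from 101161200 to 101171209.

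The AKBA list held more peaks than the DMSO list. An excess carried by a few chromosomes, as a local copy number change would give, is argued against by the 23 of 23 chromosomes that had more AKBA peaks. A more sensitive call in the AKBA library, from more reads or a stronger enrichment, remains open. The sharing of high-scoring peaks does not decide it, since 83.6% of the top score decile of the AKBA list and 83.8% of that of the DMSO list were shared. The 45.5% of DMSO peaks without an AKBA overlap do not decide it either. Their median width was 352 bp and their median score 2.72, against 847 bp and 3.35 for shared DMSO peaks, so many may lie near the threshold. A more sensitive call cannot be told apart from an effect of AKBA, which was not tested, because the depth is unknown and each condition has 1 library.

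AKBA peaks were wider than DMSO peaks, and the narrowest widths of the lists (214 and 160 bp) and their smallest gaps (857 and 641 bp) differed in nearly the same proportion. Expressed in multiples of the narrowest width, the median peak was 3.47 in the AKBA list and 3.45 in the DMSO list, which is consistent with a longer fragment length set for the AKBA library. As a test, DMSO peaks were joined across gaps of up to 856 bp and padded by 54 bp, and peaks that overlapped one to one were compared. The AKBA peak was wider by a median of 404 bp before this correction (3510 pairs, bootstrap 95% interval 367.5 to 433.5) and by 329 bp after it (3683 pairs, 298 to 369). The intervals resample peak pairs and leave out the variation between cultures. A constant pad of 54 bp and joining across 856 bp are thus argued against as the whole source of the wider pairs. The correction could not remove a widening in proportion to peak width, which the multiples of 3.47 and 3.45 leave possible. It therefore does not decide on fragment length in general. A wider region passing the threshold through depth or enrichment, and an effect of AKBA, also stay open and untested.

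The 3 highest-scoring DMSO peaks with no AKBA overlap were on chromosome 1 from 121484395 to 121485467 (score 18.7), on chromosome 7 from 61968844 to 61969608 (13.6) and on chromosome 10 from 42384628 to 42385681 (8.28). By general knowledge of hg19, and not from the files, these positions lie near centromeres, where repeats collect misplaced reads, so sequence beside the centromeres is a candidate explanation. Of the 10 highest-scoring DMSO peaks without an AKBA overlap, 4 lay within 1 Mb of a peak-free stretch of at least 3 Mb. A peak beside an unsequenced centromere must do so, and the explanation can therefore hold for at most 4 of the 10. That is fewer than the 5 that the prediction asked for, but the prediction was written for the measure first chosen. Of the DMSO peaks without an AKBA overlap outside the top 10, 4.91% met the condition. For those of the 10 that did not meet the condition, the bound argues against the explanation. For the 4 that did, the count does not decide. All 3 of the highest met the condition, and for these 3 the explanation stays open, because the condition is necessary and not sufficient. The distance to the longest stretch of each chromosome, the measure first chosen, put 1 of the 10 there and was set aside, because on chromosome 7 that stretch ran from 73.4 to 77.6 Mb.

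A further hypothesis was that AKBA peaks without a DMSO overlap are outward extensions of regions already marked in the DMSO list. It predicted that more than 50% of them would lie within 10 kb of a DMSO peak. The share was 37.6% (exact 95% interval 36.6 to 38.7%), below that bound, so most of these peaks lay farther than 10 kb from any DMSO peak. This argues only against separate peaks within 10 kb as the source of most of them. Extension that stays joined to a DMSO peak gives an overlapping peak, and overlapping peaks were left out here. The share therefore cannot decide on extension in general. The share was above the mean of 4.93% and the highest value of 6.13% in 1000 circular shifts, so the peaks were not placed independently of the DMSO list. Of the DMSO peaks without an AKBA overlap 55.5% lay within 10 kb of an AKBA peak, in a longer list.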
